A study of Mus musculus with 11 samples.

How the data were processed

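RNA was measured in 11 libraries of mouse bone marrow-derived macrophages taken from Transwell inserts, 6 treated with TGF-β1 (5 ng/mL) and 5 with TGF-β1 and hemin (10 µM), after 72 h. Per the labels' protocols, total RNA was extracted with TRIzol, checked for integrity, selected for polyadenylated RNA on oligo(dT) beads, fragmented and copied to cDNA with a uracil-marked second strand, which keeps strand information. Per the submitters' processing notes, cutadapt 1.9, FastQC 0.11.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and genome build GRCm39 were used, listed without role or order. How the counts were made, the annotation release, the strand setting and any filter are not given in the sources used here.

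The deposited table holds 25121 genes with whole-number counts per gene and library, not normalized, and with FPKM values (fragments per kilobase of transcript and library size) calculated by the authors. The ratio of count to FPKM was tested on 11672 genes with a mean count of at least 100: after scaling per library its coefficient of variation over libraries had a median of 0.0349% and was under 1% in 99.3% of genes, so 1 length per gene lies behind both. Because the strand setting is not given, genes that overlap on opposite strands are uncertain, as are near-identical copies such as the hemoglobin α genes, the paired immunoglobulin-like receptors, the Ugt1a6 genes and pseudogene families, whose reads the counting may have split. Coordinates are those of the deposited table, build GRCm39, counted from 1. A reference of an earlier build was not used here.

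Libraries were grouped by the prefix of their title, read with the 2 conditions of the design text. The plan allowed for either unit; since counts were present, edgeR was the main test as fixed before the data were examined, together with the gene lists, the markers and the rule for named genes. In R 4.3.3, edgeR 4.0.16 (filterByExpr with a minimum count of 10 and a minimum total of 15, TMM factors, quasi-likelihood F test, group as the only term, all 11 libraries) tested 15132 genes with 2-sided p-values and Benjamini-Hochberg adjustment, threshold 0.05. A stricter set also required a log2 fold change of at least 1 in size. The standard error of a log2 fold change is its size over the square root of F. Gene lists (23 pathway lists and 12 marker lists, fixed from textbook knowledge) were tested with camera of limma 3.58.1 where at least 5 members were tested, with a preset inter-gene correlation of 0.01 and again with an estimated one, and with fry, which asks whether a list's genes move 1 way and does not compare them with other genes. KEGG pathways annotated in the deposited table were tested by camera where 15 to 300 members were tested, against the 15132 tested genes. Marker levels are means of log2(FPKM + 1), compared by an exact permutation test over all 462 splits of 11 libraries into 6 and 5. Library totals and shares were compared in the same way. Benjamini-Hochberg adjustment was over the 12 lists for markers and, separately, over the library measures.

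Named genes are Hmox1; the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, mean FPKM of at least 1 and no overlap between groups, leaving out predicted genes, clone names and pseudogenes; for each pathway list up to 2 risers and 2 fallers of smallest adjusted p, or its most abundant member where none passed; and the most abundant gene of each marker list. Some of these 99 genes are described only by their list's counts. Other genes named were chosen after their values were seen.

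Total counts ran from 65.5 M to 96.6 M per library. On simulated counts for 15132 genes, drawn with the means, library sizes and dispersions of the hemin against TGF-β1 comparison, with 50 genes changed at each size, edgeR recovered 46% of changes of 1.25-fold, 74% of 1.5-fold, 80% of 2-fold and 94% of 4-fold, and 5.17% of its calls were unchanged genes. Changed genes were drawn above a floor of mean level, so recovery of the lowest genes was not measured. Camera called a simulated list raised 1.5-fold and 0 of 50 unchanged lists. The simulated genes varied independently, while estimated correlations reached 0.693 in the fixed pathway lists and 0.943 in the marker lists. The simulation therefore does not measure how often camera at its preset correlation calls unchanged lists of correlated genes. Within groups every pair of libraries differed by far more than sampling noise (chi-square of 27.0 to 186 per degree of freedom). No library is therefore a copy of another in its own group, and pairs across groups were not checked.

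Alternatives were DESeq2 1.42.0; its size factors in edgeR; no filter on low counts; genes with a mean FPKM of at least 5; robust dispersion estimates; the replicate number as a block; each library left out in turn; and limma on log2(FPKM + pseudocount), with pseudocounts of 1, 0.1 and 0.01, FPKM of at least 1 in at least 5 libraries, no filter, the stricter filter, TPM, median-of-ratios scaling, quantile normalization, array weights, robust variances and the block. Added after seeing the data were fits without hemin replicates 5 and 6, with counts thinned at random to 65.5 M per library, without ferritin, ribosomal RNA and mitochondrial rows, and with the hemoglobin level as a covariate. Functional annotation other than KEGG was not used here.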

Results

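The data are 11 poly(A)-selected RNA sequencing libraries from mouse bone marrow-derived macrophages, cells grown out of marrow and here held on a Transwell insert above primary renal proximal tubular epithelial cells. All cultures received transforming growth factor β1 (TGF-β1) at 5 ng/mL for 72 h to set up a profibrotic milieu. In 6 libraries (replicates 1 to 6) TGF-β1 was the whole treatment, and in 5 (replicates 2 to 6) hemin, the oxidised chloride form of heme, was added at 10 µM. The question the design poses is which macrophage transcripts hemin alters under TGF-β1. No group held macrophages alone, so a direct effect of hemin on them cannot be told from one through the epithelial cells. Total counts per library ran from 65.5 to 71.5 M with TGF-β1 alone and from 66.7 to 96.6 M with hemin. Levels are given as CPM after TMM normalization (counts over library size), mean ± SD. There were n = 6 libraries for TGF-β1 alone and n = 5 for hemin throughout, and a positive log2 fold change means higher with hemin. The labels do not say whether the libraries came from separate animals or cultures, so every p-value measures only the spread between these samples, which may be technical.

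The libraries separated by treatment. The first principal component of log2(FPKM + 1) held 34.9% of the variance, and its scores ran from -13.9 to -9.26 with TGF-β1 alone and from 11.2 to 18.7 with hemin. In all 11 libraries the most similar other library belonged to the same group, with correlations of 0.990 to 0.995 within groups and 0.987 to 0.991 between them. The ferritin genes Fth1 and Ftl1, which encode the chains of the iron storage shell, took 3.08 ± 0.227% of all counts with TGF-β1 alone and 5.18 ± 0.347% with hemin (2-sided exact permutation test over 462 splits, p = 0.00216, the smallest these group sizes can give). Mitochondrially encoded genes took 19.4 ± 1.29% of summed FPKM with TGF-β1 alone and 21.6 ± 1.12% with hemin (exact permutation p = 0.0130, adjusted 0.0292), and 7.99 ± 0.849% and 9.09 ± 0.647% of counts, which did not pass (exact permutation p = 0.0498, adjusted 0.0747). The share of the 10 highest genes was 22.3 ± 3.65% and 23.4 ± 0.915%, a difference within the spread between libraries (exact permutation p = 0.628). Totals were higher with hemin (exact permutation p = 0.0216), chiefly through hemin replicates 5 and 6 at 96.6 and 95.7 M counts.

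**Figure D1:**
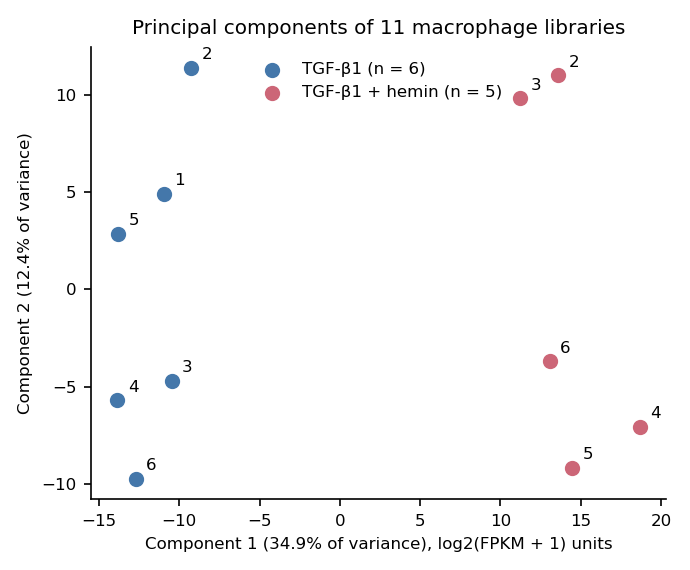
Scores of the 11 libraries on the first 2 principal components of log2(FPKM + 1), numbered by replicate, with the share of variance on each axis. Component 1 (34.9%) parts the 6 TGF-β1 libraries on the left from the 5 hemin libraries on the right, and component 2 (12.4%) parts the 6 libraries of both groups that hold hemoglobin transcripts, at the bottom, from the other 5.

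Hmox1, which encodes heme oxygenase 1, the enzyme that opens the heme ring, rose in every hemin library, from 1528 ± 88.9 to 7483 ± 179 CPM (log2 fold change 2.29, SE 0.05, a 4.90-fold rise; edgeR quasi-likelihood test, adjusted p = 7.82e-14). The gene (ENSMUSG00000005413) lies on chromosome 8 from 75820249 to 75827217, plus strand, in build GRCm39. Across the transcriptome, 2146 of 15132 tested genes changed at an adjusted p under 0.05, 1276 higher and 870 lower with hemin. Of these, 276 changed at least 2-fold, 182 higher and 94 lower. The groups did not overlap at all for 1453 of the changed genes and for 10.2% of all tested genes, where chance gives 0.433%. The balance of rises and falls depends on the scaling: in limma on FPKM, 685 genes were higher and 2186 lower without further scaling, against 1140 and 880 with median-of-ratios scaling.

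Genes of heme and iron handling rose with hemin: 16 of 30 tested members were higher, 2 were lower and 12 did not pass (16 higher and 3 lower when adjusted over the list alone; camera adjusted p = 3.53e-34). Slc40a1, which encodes the iron exporter ferroportin (ENSMUSG00000025993, chromosome 1, 45947228 to 45965683, minus strand), rose from 24.2 ± 2.35 to 113 ± 5.41 CPM (log2 fold change 2.23, SE 0.06). The falls were small. Ireb2, which encodes the iron regulatory protein IRP2, went from 52.1 ± 2.71 to 45.3 ± 1.89 CPM. Alas1, which encodes the rate-limiting enzyme of heme synthesis, went from 490 ± 27.2 to 430.1 ± 26.9 CPM. The log2 fold changes were -0.20 and -0.19 (edgeR adjusted p = 0.0117 and 0.0245).

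The list of targets of NRF2, the transcription factor of the antioxidant response, moved as a block. Of 29 tested members 27 rose and none fell (28 rose when adjusted over the list alone; camera adjusted p = 1.86e-72), with a median log2 fold change of 0.51. Gsta3, a glutathione S-transferase gene, rose 8.61-fold from 2.42 ± 0.236 to 20.8 ± 3.75 CPM. Gclm (ENSMUSG00000028124, chromosome 3, 122039206 to 122064381, plus strand), which encodes the modifier subunit of the rate-limiting enzyme of glutathione synthesis, rose 2.50-fold from 207 ± 12.7 to 518 ± 33.7 CPM (edgeR adjusted p = 1.62e-10 for Gsta3 and 1.64e-10 for Gclm). Sqstm1, which encodes the autophagy receptor p62 and sits in both this list and the lysosome list, rose from 283 ± 10.6 to 591 ± 41.2 CPM.

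Inflammatory macrophage genes were higher for 12 of 26 tested members and lower for none (13 higher and 1 lower when adjusted over the list alone; camera adjusted p = 7.08e-12). The neutrophil-attracting chemokine genes Cxcl2 and Cxcl3 rose 9.91-fold and 10.0-fold, from 0.594 ± 0.339 to 5.91 ± 1.46 CPM and from 1.56 ± 1.26 to 15.6 ± 1.86 CPM. Cxcl16 rose from 73.4 ± 2.80 to 183 ± 17.9 CPM, and Tlr2, which encodes a receptor for bacterial lipoproteins, from 96.3 ± 5.83 to 179 ± 7.87 CPM (log2 fold changes 1.32 and 0.90; edgeR adjusted p = 2.82e-10 and 3.22e-09).

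Genes of MHC class II antigen presentation also rose, 7 of 11 tested members, with none lower (7 when adjusted over the list alone; camera adjusted p = 6.82e-24). H2-Aa and H2-Ab1, which encode the chains of a class II molecule, went from 9.99 ± 1.39 to 40.4 ± 3.83 CPM and from 14.9 ± 1.65 to 54.6 ± 4.87 CPM, rises of 4.05-fold and 3.65-fold (edgeR adjusted p = 8.99e-10 and 2.82e-10). The members that did not pass numbered 4. The list's median log2 fold change was 0.32, and 0.20 on FPKM and 0.17 on TPM, where that of all genes was -0.09 and -0.13, and 0.30 with median-of-ratios scaling.

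Among matrix-degrading proteases, 9 of 16 tested members rose and 1 fell (10 and 1 when adjusted over the list alone; camera adjusted p = 3.43e-13). Mmp14, which encodes a membrane-bound collagenase, rose 3.66-fold from 38.8 ± 5.95 to 142 ± 21.4 CPM. Mmp12, the macrophage elastase gene, rose 2.16-fold from 2128 ± 125 to 4589 ± 489 CPM. Mmp9, a gelatinase gene, was the member that fell, from 8.44 ± 2.51 to 4.27 ± 2.17 CPM (log2 fold change -0.98, SE 0.31; edgeR adjusted p = 0.0439).

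Genes known from scar-associated macrophages were higher for 11 of 15 tested members and lower for none (11 when adjusted over the list alone; camera adjusted p = 5.28e-11, and adjusted p = 0.0941 with an estimated correlation). Lgals3, which encodes galectin 3, rose from 1995 ± 133 to 3819 ± 317 CPM, and Vim, which encodes vimentin, from 2328 ± 72.1 to 3699 ± 264 CPM. In the lysosome and autophagy list 11 of 29 tested members rose and 1 fell (13 and 1 when adjusted over the list alone; camera adjusted p = 8.22e-05, and adjusted p = 0.162 with an estimated correlation). The call was also lost in limma after quantile normalization (camera adjusted p = 0.0801). The list's median log2 fold change, 0.09, turned to -0.01 on FPKM as deposited and to -0.04 on TPM, where the median of all genes stood at -0.09 and -0.13. Gabarapl1, an autophagosome gene, rose from 60.1 ± 3.93 to 79.0 ± 3.81 CPM, while Ctsd, which encodes the lysosomal protease cathepsin D, fell from 15776 ± 1351 to 12848 ± 570 CPM (edgeR adjusted p = 0.00277).

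Type I interferon response genes were lower with hemin for 19 of 29 tested members and higher for none (24 lower when adjusted over the list alone; camera adjusted p = 1.49e-14, and adjusted p = 0.0941 with an estimated correlation). The median log2 fold change was -0.74. Irf7 (ENSMUSG00000025498, chromosome 7, 140842619 to 140846394, minus strand), which encodes a transcription factor that amplifies interferon production, fell from 12.0 ± 5.81 to 3.04 ± 0.734 CPM, 3.96-fold lower. Oas1a, which encodes a sensor enzyme for viral RNA, fell from 43.1 ± 4.46 to 25.7 ± 0.618 CPM, and Irf9, part of the interferon-activated transcription complex, from 34.4 ± 3.10 to 20.1 ± 2.39 CPM (edgeR adjusted p = 8.14e-05, 2.10e-06 and 1.12e-05). TGF-β1 replicate 4 had the highest Irf7 level, 22.9 CPM, and was the sole library with counts of Ifnb1, the interferon β gene, at 0.825 CPM. Without it 15 of these 19 members still fell, with a median log2 fold change of -0.61.

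The TGF-β response list was lower with hemin as well: 11 of 26 tested members fell and 2 rose (15 and 2 when adjusted over the list alone; camera adjusted p = 6.30e-08). Pmepa1, which encodes a feedback inhibitor of TGF-β signalling, fell from 324 ± 23.5 to 176 ± 11.5 CPM, and Id3, an inhibitor of differentiation factors, from 81.8 ± 7.41 to 45.6 ± 3.53 CPM (log2 fold changes -0.88 and -0.84; edgeR adjusted p = 2.95e-08 and 2.93e-07). The members that went the other way were Spint1, a protease inhibitor gene (log2 fold change 0.70), and Tgfbi, which encodes a secreted matrix protein and rose from 1040 ± 56.6 to 1461 ± 65.2 CPM.

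With camera at its preset correlation, 9 of the 23 fixed lists were called, 7 higher and 2 lower. With an estimated correlation, 6 calls held: NRF2 targets, heme and iron handling, MHC class II (each adjusted p at or below 0.000341), TGF-β response (0.000851), proteases (0.00149) and inflammatory genes (0.0106). Of 100 splits of these libraries into 6 and 5, 30 gave 9 or more lists at the preset correlation. Of those 30, 24 were the real split or splits with 0, 1 or 4 hemin libraries in the group of 5. The other 6 came from the 73 splits with 2 or 3, which keep less of the treatment contrast.

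**Figure D2:**
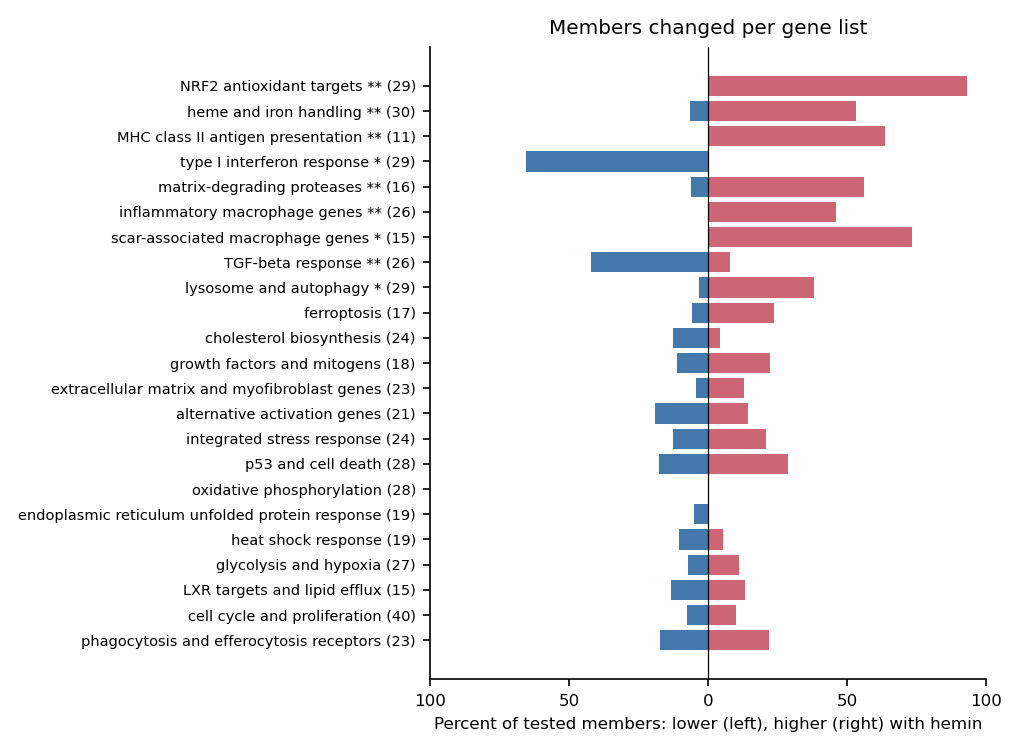
Percent of the tested members of each fixed gene list (number tested in brackets) that were lower (blue, left) or higher (red, right) with hemin at an edgeR adjusted p under 0.05. A star marks an adjusted camera p under 0.05 at the preset correlation and a second star the same with an estimated correlation; 27 of 29 NRF2 targets rose and 19 of 29 interferon genes fell.

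The remaining 14 lists were not called by camera, though single members changed in most of them. By fry, the ferroptosis list and the p53 and cell death list were called (fry adjusted p = 4.40e-05 and 0.0441). In the alternative activation list 3 of 21 members rose and 4 fell (5 and 5 when adjusted over the list alone; camera adjusted p = 0.393), and its median and mean log2 fold changes, 0.12 and 0.28, lay opposite in sign to the camera direction. On FPKM and TPM the list's median, -0.08 and -0.12, lay close to that of all genes (-0.09 and -0.13). Arg1 (chromosome 10, 24791119 to 24803382, minus strand), which encodes arginase 1, fell 2.39-fold from 2897 ± 476 to 1213 ± 167 CPM, and Tgm2, which encodes a transglutaminase, fell from 1300 ± 59.2 to 750.2 ± 26.0 CPM (edgeR adjusted p = 8.97e-07 and 6.64e-09). Clec10a, a lectin receptor gene, rose from 3.56 ± 0.452 to 5.62 ± 0.810 CPM.

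Growth factor and mitogen genes went both ways, with 4 of 18 higher and 2 lower (5 and 3 when adjusted over the list alone; camera adjusted p = 0.393). Pdgfb and Igf1, which encode growth factors for mesenchymal cells, rose 2.11-fold each, to 46.7 ± 3.74 and 423 ± 47.6 CPM from 22.1 ± 1.43 and 201 ± 14.4 CPM. Fgf2 fell 3.22-fold from 7.19 ± 1.05 to 2.24 ± 0.550 CPM and Vegfa, the main angiogenic factor gene, 1.58-fold from 107 ± 19.7 to 67.8 ± 4.49 CPM. In the extracellular matrix list 3 of 23 members rose and 1 fell (3 and 5 when adjusted over the list alone; camera adjusted p = 0.393). The member that fell, Timp1, which encodes an inhibitor of metalloproteinases, went from 18.6 ± 4.59 to 8.10 ± 1.88 CPM. Col6a1 rose from 1.65 ± 1.23 to 4.25 ± 1.15 CPM, but its groups overlapped, with TGF-β1 replicate 6 at 4.10 CPM. The more abundant Col1a1 and Col1a2 did not pass over all genes. Their means were lower with hemin, 22.7 ± 9.72 to 12.9 ± 3.14 FPKM and 6.27 ± 2.44 to 3.84 ± 0.966 FPKM. The list's median log2 fold change was -0.22. Acta2, the most abundant gene of the fibroblast markers, stood at 63.1 ± 20.2 and 61.7 ± 14.6 CPM. Which cells supply the transcripts of this list was not tested.

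Among phagocytosis receptors 5 of 23 rose and 4 fell (the same numbers when adjusted over the list alone; camera adjusted p = 0.887). Cd36, a scavenger receptor gene, rose from 535 ± 54.9 to 940.0 ± 108 CPM, and Itgb5, an integrin gene, fell from 1279 ± 43.7 to 1052 ± 49.8 CPM. Ferroptosis genes were higher for 4 and lower for 1 of 17 (the same numbers when adjusted over the list alone; camera adjusted p = 0.109), with Slc3a2, the partner chain of the cystine importer, up from 309 ± 13.5 to 469 ± 26.3 CPM. The integrated stress response list had 5 of 24 higher and 3 lower (7 and 4 when adjusted over the list alone; camera adjusted p = 0.393), led by Atf3, a stress-induced transcription factor gene, with a log2 fold change of 0.83. For LXR targets the numbers were 2 higher and 2 lower of 15 (4 and 4 when adjusted over the list alone; camera adjusted p = 0.852), with the lipid exporter gene Abcg1 at 0.41 and the apolipoprotein E gene Apoe at -0.60 on the log2 scale.

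None of the 28 tested oxidative phosphorylation genes passed the edgeR test, over all genes or adjusted over the list alone (camera adjusted p = 0.481), and Atp5f1a, an ATP synthase gene and its most abundant member, was at 714 ± 35.8 and 690.3 ± 16.7 CPM. The wider KEGG set of the same name, by contrast, had 19 of 125 members higher and 0 lower (camera adjusted p = 0.00783, and adjusted p = 0.771 with an estimated correlation). Its members were not split here into respiratory chain genes and proton pump genes, the latter higher for 11 of 19. Its rises therefore cannot be placed in the respiratory chain. In the cell cycle list 4 of 40 rose and 3 fell (6 and 5 when adjusted over the list alone; camera adjusted p = 0.887). Pcna, the replication clamp gene, rose from 267 ± 18.3 to 340 ± 31.4 CPM, and Ccnd1, the cyclin D1 gene, fell from 303 ± 13.2 to 245 ± 9.14 CPM. Glycolysis and hypoxia genes were higher for 3 and lower for 2 of 27 (3 and 3 when adjusted over the list alone; camera adjusted p = 0.852), with the phosphofructokinase gene Pfkp at 0.52 and the hexokinase gene Hk2 at -0.38 on the log2 scale. The p53 and cell death list held 8 rises and 5 falls among 28 (9 and 5 when adjusted over the list alone; camera adjusted p = 0.481), among them Mlkl, the executor of necroptosis, at 0.44. Heat shock genes showed 1 rise and 2 falls among 19 (1 and 3 when adjusted over the list alone; camera adjusted p = 0.764), with the cochaperone gene Bag3 at 0.31. Cholesterol synthesis genes showed 1 rise and 3 falls among 24 (1 and 4 when adjusted over the list alone; camera adjusted p = 0.393), with Insig1, a brake on sterol synthesis, at -0.31. Of 19 unfolded protein response genes Herpud1, a degradation factor, alone passed at -0.21 (0 when adjusted over the list alone; camera adjusted p = 0.517). The median, mean and camera direction differ in sign for the growth factor, phagocytosis, LXR, heat shock, ferroptosis, glycolysis and cell cycle lists, whose medians lie between -0.10 and 0.08.

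The largest rises among genes with a mean FPKM of at least 1 whose groups did not overlap were Tnfsf4, which encodes the costimulatory ligand OX40L (0.267 ± 0.247 to 4.63 ± 0.602 CPM, log2 fold change 4.11), and Acod1, which makes itaconate (4.95 ± 2.62 to 57.7 ± 1.74 CPM, 3.54). Ppbp, a platelet chemokine gene, followed at 3.41, and then Cxcl3, Cxcl2 and Gsta3. Next came Slc39a4, a zinc importer gene, at 3.10, Clec4n, which encodes the fungal receptor dectin 2, at 2.81 (28.1 ± 2.46 to 198 ± 14.2 CPM), the complement factor B gene Cfb at 2.68, and the myeloid receptor gene Treml4 at 2.66. The largest falls under the same limits were Rgs16, a regulator of G protein signalling (7.83 ± 1.54 to 1.57 ± 0.433 CPM, -2.32), the interferon-induced gene Rtp4 at -2.25, Irf7 at -1.99 and the Notch target Hes1 at -1.61. Ifi27l2a, Cd38, Ltbp2, Serpinb1a, Plppr3 and Cdh1 lay between -1.48 and -1.36. All 20 had an edgeR adjusted p of 0.00441 or less.

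**Figure D3:**
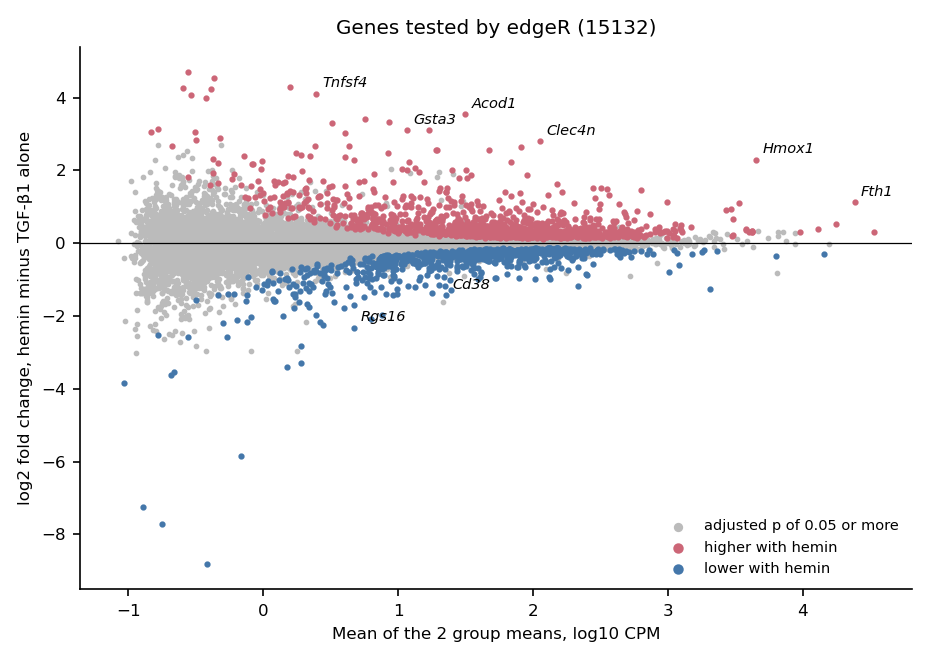
Log2 fold change (hemin minus TGF-β1 alone) against mean level on a log10 CPM axis for the 15132 genes tested by edgeR, with the 1276 genes higher with hemin in red and the 870 lower in blue. Hmox1 stands at 2.29 and Clec4n at 2.81; the lowest points, Gm16332, Grin3b and Garem2, had no count in any hemin library, so their fitted fold depends on the prior count.

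**Figure D4:**
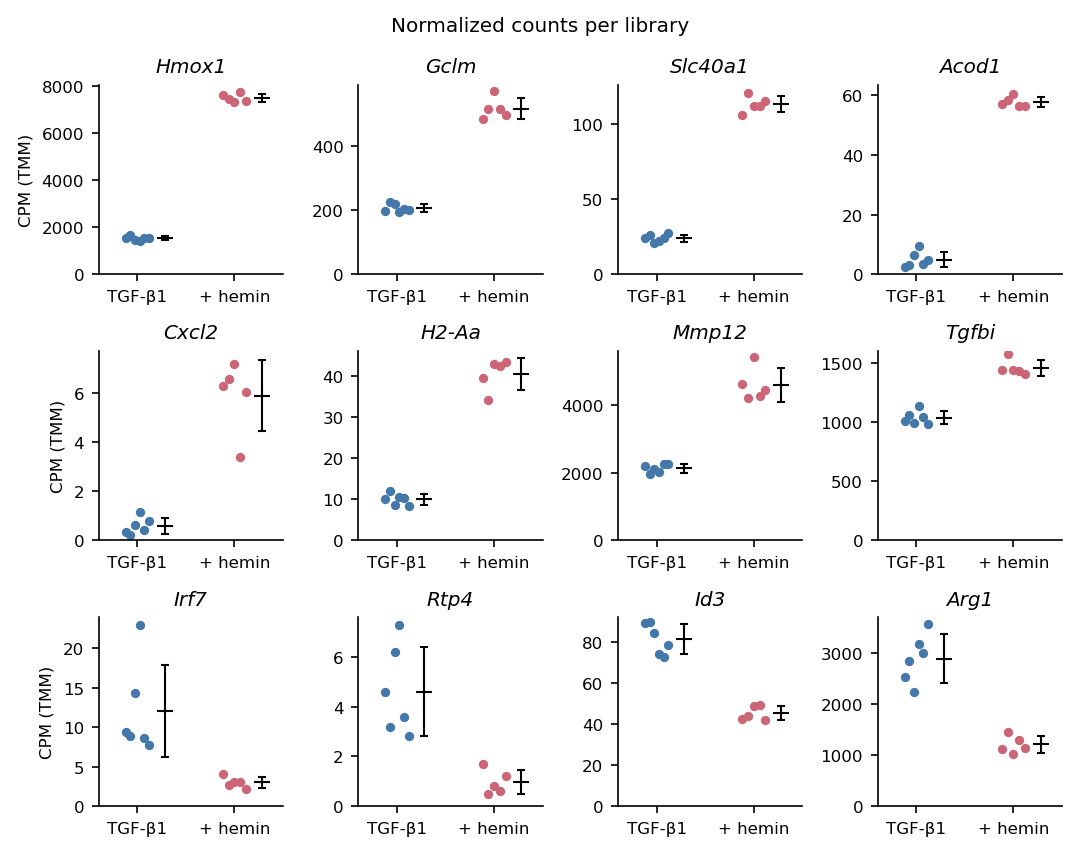
CPM (TMM normalized) of 12 genes in each of the 6 TGF-β1 (blue) and 5 hemin (red) libraries, with mean and SD in black. In every panel all hemin libraries lie on 1 side of all TGF-β1 libraries, as for Hmox1 (1528 ± 88.9 against 7483 ± 179) and Irf7 (12.0 ± 5.81 against 3.04 ± 0.734).

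A search over 300 KEGG pathways annotated in the deposited table called 55 higher and 6 lower by camera, and 13 held with an estimated correlation. Ferroptosis, which in KEGG holds ferritin, Hmox1 and glutathione genes, had 16 of 38 members higher and 1 lower (adjusted p = 4.14e-21, and 0.00890 with an estimated correlation). Mineral absorption (11 of 33 higher, 2 lower; adjusted p = 1.52e-12, and 0.00141 with an estimated correlation), Porphyrin metabolism (8 of 28 higher, 1 lower; 1.06e-09, and 0.0226) and Glutathione metabolism (14 of 50 higher, 4 lower; 5.13e-09, and 0.0276) were called too. Rheumatoid arthritis, a pathway built of cytokine, class II and proton pump genes, had 31 of 66 members higher and 3 lower (3.59e-11, and 0.0184). Lysosome (41 of 122 higher, 9 lower) was called at 4.38e-05 but had adjusted p = 0.321 with an estimated correlation. The TGF-beta signaling pathway had 17 of 79 members lower and 5 higher (adjusted p = 0.000850, and 0.0825 with an estimated correlation), and the Wnt signaling pathway 21 of 120 lower and 4 higher (0.00879, and 0.206).

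Macrophage markers went both ways: 4 of 14 rose and 3 fell in edgeR (5 and 3 when adjusted over the list alone). Their mean log2(FPKM + 1) was 7.73 ± 0.07 with TGF-β1 alone and 7.65 ± 0.04 with hemin (exact permutation test, adjusted p = 0.169 over 12 marker lists). Of the other lists 1 passed: megakaryocyte and platelet markers stood at 1.88 ± 0.08 and 2.86 ± 0.06 (exact permutation adjusted p = 0.0260), through the chemokine genes Pf4 (74.1 ± 11.8 to 229 ± 28.7 CPM) and Ppbp, while Itga2b and Gp1bb were near 0 in both groups. Endothelial markers were 0.51 ± 0.04 and 0.43 ± 0.03 (exact permutation adjusted p = 0.0519, and 0.0260 with a pseudocount of 0.1). Mast cell and basophil markers were 0.12 ± 0.05 and 0.04 ± 0.03 (exact permutation adjusted p = 0.104). Renal tubular markers were low, 0.47 ± 0.12 and 0.44 ± 0.12 (exact permutation adjusted p = 0.732). The most abundant, the E-cadherin gene Cdh1, fell from 25.6 ± 3.62 to 9.95 ± 2.06 CPM. Havcr1 went the other way, from 2.23 ± 1.03 to 4.29 ± 2.38 FPKM, and Epcam, Lrp2 and Hnf4a were near 0 in both groups. Which cells supply the Cdh1 transcripts was not tested. By the same exact test the dendritic cell (0.343), monocyte (0.704), neutrophil (0.636), osteoclast (0.704), lymphoid (0.704), fibroblast (0.472) and erythroid (0.636) lists did not pass, the last with levels of 1.16 ± 1.22 and 1.93 ± 1.75. By camera, 0 of the 8 marker lists with at least 5 tested members were called (adjusted p from 0.685 to 0.906).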

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

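Of the tests in this part, those of replicate 4, of dendritic cells, scaling and depth for MHC class II genes and of both hemoglobin explanations were chosen after the result was seen. In 238 groups of values, a library lay far from the rest of its own treatment group in 21, where chance gives about 1 in 20, or 11.9.

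In TGF-β1 replicate 6 the summed hemoglobin transcripts reached 121 CPM, against 0.0565 to 31.0 in the other TGF-β1 libraries, and Hba-a1 alone 42.1 CPM. Across both groups 6 libraries (TGF-β1 replicates 3, 4 and 6 and hemin replicates 4, 5 and 6) had 20.4 to 319 CPM and the other 5 at most 1.13 CPM. Component 2 of all tested genes parts these 2 sets of libraries by a gap of 6.55. A wider difference between them stays open: without the erythroid genes the sets overlapped on components 1 to 3 (largest gap -2.40), which leaves room for a smaller difference. Carried-over erythroid cells may be the source, since Alas2, an erythroid heme synthesis gene outside the hemoglobins, had at least 21 counts in each of the 6 libraries and at most 4 in the others. Leakage of RNA from another library was not tested, and no biological explanation was tested.

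The type I interferon list was lower with hemin, a call lost with an estimated correlation (camera adjusted p = 0.0941), and TGF-β1 replicate 4 held the highest levels of Irf7 (22.9 CPM), Usp18 (14.8 CPM) and Ifi44 (11.4 CPM). That library is argued against as the whole cause: without it the list's median log2 fold change was -0.61 and its mean level still parted the groups (exact permutation p = 0.00794, the smallest for 5 against 5). Library scaling is argued against too, since the highest median over the scalings was -0.51. The difference may therefore go with hemin, as a hypothesis, with 6 of 6 TGF-β1 libraries above every hemin library; a batch shared by a treatment group stays open.

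MHC class II genes were higher with hemin, with a median log2 fold change of 0.32. Depth is argued against, since without the 2 deepest libraries, which leaves hemin totals of 66.7 M to 74.3 M, the median was 0.33. Library scaling could not be settled. The limit set was a list median above 0.20 under every scaling, and the lowest was 0.17, on TPM. The list's median did lie above that of all genes under every scaling. A factor per library shifts both alike, so that gap cannot decide the question. On TPM the list's median was 0.17 against -0.13 for all genes, on FPKM 0.20 against -0.09, and after quantile normalization 0.26 against -0.02. Under the remaining scalings besides the main one it was 0.30 to 0.31. The size of the rise still moved with the scaling. A larger share of dendritic cells could not be settled: 4 tested markers had a median of -0.042 but ranged from -0.47 to 0.59. With Itgax set aside as a macrophage gene too, 1 had a mean count of at least 50, too few to decide. Batf3 went from 0.756 ± 0.215 to 1.05 ± 0.109 FPKM. Clec9a (0.158 to 0.106 FPKM) and Zbtb46 (0.0245 to 0.0185 FPKM) were near 0 and did not rise. An effect of hemin on the macrophages, direct or through the epithelial cells, may be the cause. It remains as open as a larger share of dendritic cells.

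In TGF-β1 replicate 2 the 10 highest genes took 29.6% of FPKM (19.8 to 21.9% in the rest of its group) and the ribosomal RNA gene Rn18s-rs5 2.94% of counts (0.241 to 0.756%), with Pmepa1 at 367 CPM (299.5 to 325) and Fgf2 at 9.30 CPM (6.48 to 7.03). TGF-β1 replicate 6 also stood high in Col6a1 (4.10 CPM), Apoc2 (55.5), Aldoc (68.1), Hk2 (108) and Pf4 (96.3). TGF-β1 replicate 4 was low in Mmp9 (3.64 CPM, the others 8.51 to 10.8) and high in Ighm (2.74 CPM) and in neutrophil markers (0.50 as mean log2(FPKM + 1)), and TGF-β1 replicate 1 was low in Cd38 (29.0 CPM). Hemin replicate 3 was high in Serpinb1a (6.36 CPM), Cdh1 (13.5) and Tgfbi (1575), while hemin replicate 4 was low in Plppr3 (3.47 CPM) and high in Pfkp (129.8) and Pcna (395).

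Of the 462 splits of the 11 libraries into 6 and 5, 100 were drawn, the real one included. As many changed genes came from 1 (2146, highest other 1179), and as many changed at least 2-fold from 1 (276, highest other 151). As many KEGG pathways came from 2 (61, highest other 69), and as many lists with an estimated correlation from 1 (6, highest other 5). A random labelling of these libraries thus seldom reaches such counts. Relabelling cannot exclude a batch shared by a treatment group, nor show that the libraries are separate cultures. For the number of lists at the preset correlation a random labelling stays open, since 30 splits gave 9 or more, with 12 as the highest. Of the 30, 24 hold 0, 1, 4 or 5 hemin libraries in the group of 5, which keeps more of the treatment contrast than 2 or 3 do. A group of 5 with 1 hemin library does not keep most of that contrast. Such a split gave, for example, 12 lists with 0 changed genes. Of the 73 splits with 2 or 3, 6 gave 9 or more, with 11 as the highest.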

How the results depend on the processing

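The fits without the 2 deepest libraries, with thinned counts, without ferritin, ribosomal RNA and mitochondrial genes and with the hemoglobin level as a covariate were chosen after the data were seen. Hmox1 kept its rise in all of its refits, with log2 fold changes from 2.15 to 2.31. Against 2146 changed genes, DESeq2 gave 2691 (2134 of them shared), edgeR with its size factors 2148, and limma with array weights 3286. Leaving out 1 library gave 1704 to 2169 genes, 1018 to 1247 higher, 686 to 923 lower, 253 to 288 changed at least 2-fold, 9 lists each time and 58 to 65 pathways. Against 1276 higher and 870 lower, limma on FPKM gave 685 and 2186, with a pseudocount of 0.1 683 and 2197, of 0.01 682 and 2199, without a filter 659 and 1626, at a mean FPKM of at least 5 539 and 1572, on TPM 425 and 1587. With array weights it gave 743 and 2543, and robust 675 and 2183. FPKM and TPM without a factor for composition shift the median of all genes to -0.09 and -0.13. The share higher was 59.5% in edgeR, 23.9% on FPKM, 21.1% on TPM, 49.5% after quantile normalization and 56.4% after median-of-ratios scaling. Without the 2 deepest libraries 565 were lower, with fewer samples. Changes of at least 2-fold, 276 in edgeR, numbered 57 at a mean FPKM of at least 5 (fewer genes tested), and in limma 74 on FPKM, 137 and 143 with pseudocounts of 0.1 and 0.01, which shrink folds of low genes less. They numbered 69 without a filter, 44 at a mean FPKM of at least 5, 108 on TPM, 76 with median-of-ratios scaling, 72 after quantile normalization, 75 with array weights and 70 robust. With the replicate block edgeR gave 1532 genes (1457 shared), and limma 521 higher and 79 changed at least 2-fold. Pairing by number has little footing, with correlations from -0.09 to 0.11 and 2 of 5 pairs over 0.1. Pathways, 61 in edgeR, numbered 105 and 101 without a filter (edgeR and limma), 35 and 38 at a mean FPKM of at least 5, and 13 with an estimated correlation. With a pseudocount of 0.1, 2 marker lists passed instead of 1, the endothelial list being added (exact permutation adjusted p = 0.0260). Where no reason is given the cause was not tested. Called lists kept their call in 302 of 306 reruns, and 6 of the 9 in every one. The interferon and scar-associated lists lost it with an estimated correlation, and the lysosome list there and after quantile normalization. Other lists gained a call in 10 reruns. The lists called numbered 11 with fry and in edgeR at a mean FPKM of at least 5, 10 in limma at that filter and 13 in limma without a filter. After quantile normalization 9 were called although the lysosome list was lost, so another list gained a call there. Of 3067 reruns of 99 named genes, 2939 kept their side of the threshold, 112 lost it, 16 gained it and 0 reversed. Thinning every library to 65.5 M counts, close to the TGF-β1 totals, gave 2135 genes, and no lower depth was run.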

Other observations

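All gene families in this part were chosen after the data were seen, so their p-values measure no more than how far they stand out in these data. Ranges over the scalings include FPKM and TPM, where genes of low FPKM are left out as well, so they are not due to scaling alone.

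Lectin receptors of the Clec4 cluster were higher for 6 of 7 tested genes (lowest median over the scalings 0.84; camera adjusted p = 1.54e-33, and 0.000140 with an estimated correlation), among them Clec4d at 1.51. Paired immunoglobulin-like receptors were higher for 11 of 12 (medians from 0.75 to 1.05 over the scalings, camera adjusted p = 4.87e-21, and 0.00177 with an estimated correlation). Pirb was at 1.14, although the sequences of these receptors are so alike that reads cannot be assigned with certainty. Targets of the aryl hydrocarbon receptor were higher for 5 of 6 (medians from 1.00 to 1.41 over the scalings, camera adjusted p = 6.24e-08, and 0.00177 with an estimated correlation). The receptor's repressor gene Ahrr was at 1.53 and Cyp1b1, a cytochrome P450 gene, at 1.29. Nqo1, another that rose, is also in the NRF2 list. The member that did not pass was Tiparp at 0.11 (edgeR adjusted p = 0.212). Glutathione S-transferase genes were higher for 6 of 19 (medians from 0.19 to 0.34 over the scalings, camera adjusted p = 4.30e-11, and 0.00110 with an estimated correlation). Among these, Gsta3, Gstm1 and Mgst1 are also in the NRF2 list. NF-κB members and feedback genes were higher for 11 of 19 (medians from 0.20 to 0.41 over the scalings, camera adjusted p = 2.63e-10, and 0.00192 with an estimated correlation). Nfkbiz was at 1.20, from 1.31 ± 0.461 to 3.02 ± 0.771 CPM. Members that did not pass included Nfkbia at 0.09, Tnfaip3 at 0.21, Rela at 0.15, Nfkb1 at 0.01 and Rel at -0.18. Their edgeR adjusted p-values were 0.306, 0.113, 0.0629, 0.951 and 0.225. Interferon-inducible GTPase genes were lower for 7 of 18 (medians from -0.45 to -0.24 over the scalings, camera adjusted p = 2.37e-07, and 0.0110 with an estimated correlation), with Gbp9 at -1.21. A group of Egr, Id and Notch target genes and the ligand gene Bmp2 was lower for 6 of 10, with Egr1 at -0.95. Its medians ran from -0.66 to -0.45 over the scalings (camera adjusted p = 4.73e-06, and 0.0144 with an estimated correlation). Proton pump genes were higher for 11 of 19 (medians from 0.07 to 0.21 over the scalings; camera adjusted p = 5.62e-06, but adjusted p = 0.107 with an estimated correlation). Complement genes were higher for 5 and lower for 1 of 12 (camera adjusted p = 0.0136, but adjusted p = 0.107 with an estimated correlation), with medians from -0.08 to 0.24 over the scalings. None of 82 ribosomal protein genes passed in edgeR (camera adjusted p = 0.912).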
